A study of Mus musculus with 12 samples.

How the data were processed

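Gene expression was measured by RNA sequencing in hematopoietic stem cells sorted with the SLAM markers from db mice, which carry a mutation of the leptin receptor gene Lepr, and from littermate control mice, all 4 months old. Cells were cultured for 48 h, 1000 per culture, with stem cell factor and thrombopoietin at 20 ng/mL each, with or without 100 µM buthionine sulfoximine (BSO), an inhibitor of glutathione synthesis. Amplified cDNA was made into Nextera XT libraries and read as pairs of 75 bp, per the labels' protocols. The 12 libraries form 4 groups of 3, named control vehicle, control BSO, db vehicle and db BSO. The labels do not say whether libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

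The deposited table holds TPM values (transcript abundance scaled to a fixed total) for 28987 Ensembl genes, with 1 column per library and no pooled column. The values were made with kallisto against mm10, per the submitters' processing notes. The version, the annotation, any filter and the way transcripts were summed to genes are not given in the sources used here. Each library's values sum to between 96.9% and 97.1% of that total, for a reason not given. TPM keeps no read depth, so the depth behind a value is unknown and no count test, counting interval or detection floor is given. TPM values are shares of a library, so a gene that takes a larger share lowers all others.

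Gene symbols and coordinates were taken from GENCODE mouse release M21 on the mm10 assembly, which matched 27458 of the 28987 identifiers. The kit does not mark strand and pseudoalignment can split reads between near-identical sequences, so values of Ftl1 and its processed copies, of glutathione transferase paralogs and of H2-Q genes are uncertain in how they are shared out.

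Tests were run on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 12 libraries in the fit, a variance trend and no replicate block. The 10333 genes with a mean of at least 1 TPM were tested in 5 contrasts, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The contrasts were db against control in each treatment, BSO against vehicle in each genotype, and the difference of the BSO effects. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Gene lists were compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, adjusted over lists within each contrast. Of 36 lists fixed beforehand, 33 had at least 3 tested members. The FOXO family, endothelial and stromal, and sex-linked lists had fewer and were not tested. Each list was also tested with an estimated correlation and with fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

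The groups, tests, lists, alternatives and rule for named genes were fixed before the data were examined. The rule took, in each contrast, the 10 genes with the largest change in each direction among those past the threshold, with at least 5 TPM in the higher group and no overlap between replicates, leaving out predicted genes, receptor segments and pseudogenes. Where fewer than 5 qualified, the 5 with the smallest p were given as values. It added up to 4 members of each list with the smallest p and a set of genes always given (Foxo1, Foxo3, Foxo4, Gclc, Gclm, Nqo1, Hmox1, Slc7a11, Txnip, Cdkn1a, Lepr, Procr and Mecom). This named more genes than a text can hold. It was narrowed, after the values had been seen, to the largest changes, the genes always given, and the list members of lists past the threshold, of the FOXO targets and of the stem cell genes. All of these were carried through the alternatives, except the fit of only the 2 groups compared and gene-by-gene sample weights, which gave counts alone. The text prints the genes always given, the largest changes and the genes with the smallest p, but of the list members mainly those past the threshold, a further choice made after the values were seen, so list members that did not pass are mostly not printed.

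The same test was checked on simulated data for the 10333 genes, with 200 genes changed by known amounts. A further small set of genes was raised together for a check of the list test. It is left out of the shares and counts below. Noise was drawn independently for each gene, with no structure shared between genes or libraries. Only genes with a mean log2(TPM + 1) over 2 were changed. The shares recovered may therefore not hold for the real libraries or for low genes. At a log2 change of 1, it recovered 52% of changed genes for db against control with vehicle, 66% for BSO in control cells, 58% for BSO in db cells, 54% for db against control with BSO and 34% for the difference of BSO effects. At a log2 change of 2 the shares were 92%, 98%, 94%, 98% and 80%. The smallest change simulated, 0.5, gave 20%, 18%, 26%, 20% and 4%. The calls of unchanged genes numbered 17, 7, 11, 7 and 2. For db against control with vehicle, the 17 stood beside 10, 26, 46 and 49 genes recovered at changes of 0.5, 1, 2 and 3. For BSO in db cells, the 11 stood beside 13, 29, 47 and 50. In both, unchanged genes were a larger share of these calls than the adjusted p threshold aims at.

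Alternatives covered the pseudocount, the filter on low values, the variance trend, 2 scalings between libraries, sample weights, the libraries in the fit, a replicate block, the set test and the omission of each library in turn. Libraries of a group correlated at 0.967 to 0.985 on the log2 scale over genes, and no 2 libraries were identical. All libraries share a sequencing lane, but the 6 control libraries carry one i5 index and the 6 db libraries another, so an effect of the index cannot be separated from genotype. Likewise, no i7 index was used for both vehicle and BSO libraries, so an effect of that index cannot be separated from treatment. No library was left out.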

Results

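The series measured gene expression in cultured SLAM hematopoietic stem cells (HSC) from db and control mice, with and without BSO, under a title on FOXO activity in hyperglycemia. Values are means ± SD in TPM over 3 libraries per group, and log2 fold changes are given ± SE with adjusted p-values from limma. Lists carry the adjusted p from camera and then the adjusted p with an estimated correlation. Read depth is unknown. The libraries listed 10579 ± 58.0 genes at 1 TPM or more in control vehicle, 10181 ± 154 in control BSO, 10188 ± 128 in db vehicle and 9972 ± 295 in db BSO. With 3 libraries against 3, the smallest two-sided p of an exact permutation test is 0.1, which db against control with vehicle and BSO against vehicle in control cells both reached for this measure. Lepr, the mutated gene (chromosome 4, 101717404 to 101815352, plus strand), lay below the filter, at 0.323 TPM over all libraries, so it gives no check on the genotype labels. Among Y-linked genes, Kdm5d was listed at 0 in each library and Ddx3y stayed at or below 0.102 TPM. Uty lay between 0.309 and 0.958 TPM, and Eif2s3y reached 1.15 TPM in control BSO replicate 2 and 0.518 TPM in control BSO replicate 1. The values of Kdm5d and Ddx3y argue against male animals, whereas the low values of Uty and Eif2s3y are left unexplained.

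The first comparison asked how db HSC differed from control HSC after culture without BSO. Genes that rose in db cells included 3 markers of the megakaryocyte lineage. Serpine2, a protease inhibitor (chromosome 1, 79794197 to 79861180, minus strand), rose from 8.999 ± 5.03 to 102 ± 22.5 TPM, a log2 fold change of 3.45 ± 0.37 with an adjusted p of 0.00147. Pf4, a platelet chemokine (chromosome 5, 90772435 to 90773383, plus strand), rose from 259 ± 216 to 1851 ± 282 TPM (3.14 ± 0.45, adjusted p = 0.00612). Of 15 tested megakaryocyte markers, 3 rose, namely Pf4, the platelet integrin subunit Itga2b (1.71 ± 0.28, adjusted p = 0.0108) and Rab27b, which acts in platelet granule release (1.42 ± 0.23, adjusted p = 0.0108). Adjusted over the list alone, 11 rose and 1 fell. The list's median lay 1.40 above that of all genes (camera adjusted p = 3.70e-15, and adjusted p = 0.212 with an estimated correlation). Rap1b, a small GTPase used in platelet aggregation, rose from 261 ± 69.1 to 1026 ± 312 TPM, and Pls1, Timp3, Rgs10, Clu, Alox5 and F2rl2 rose by 1.82 to 2.78. Il1b, encoding interleukin 1 beta, was listed at 0 in each control vehicle library and at 11.4, 10.3 and 2.66 TPM in the db vehicle libraries (adjusted p = 0.00288).

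Genes lower in db vehicle cells included Vim, the intermediate filament protein vimentin, which fell from 149 ± 18.7 to 64.7 ± 5.96 TPM (−1.19 ± 0.16, adjusted p = 0.00388), and Myl10, a myosin light chain gene, which fell from 17.5 ± 3.35 to 3.52 ± 1.06 TPM. Hlf, a transcription factor of HSC, fell from 11.3 ± 1.01 to 4.84 ± 0.95 TPM (−1.08 ± 0.22, adjusted p = 0.0494). Padi4, Tspan17, Cpne8, Copz2, Tmem98, Wbp1 and Tnfsf13os also fell, by between 0.99 and 1.57 on the log2 scale. Hlf was the 1 of 24 tested HSC genes that fell, and the HSC list did not pass (0.636, and 0.988 with an estimated correlation). In all, 35 genes rose and 18 fell, 53 of 10333. At an unadjusted p under 0.05 there were 1512, and there the balance was the opposite, with 370 higher and 1142 lower.

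None of the 5 lists past the camera threshold in this comparison held with an estimated correlation. Of 17 genes of the unfolded protein response, 1 rose, the chaperone cofactor Sdf2l1 (0.76 ± 0.12, adjusted p = 0.00726), with a list adjusted p of 3.39e-05 (adjusted p = 0.428 with an estimated correlation). Of 78 nuclear oxidative phosphorylation genes, 1 rose, the ATP synthase subunit gene Atp5f1 (0.47 ± 0.07, adjusted p = 0.00726), with 7.06e-08 for the list (adjusted p = 0.428 with an estimated correlation). None of the 6 erythroid markers passed singly, with 5 above 0 and 0.0276 for the list (adjusted p = 0.428 with an estimated correlation). None of the 14 myeloid markers passed singly, with 0.0119 for the list (adjusted p = 0.936 with an estimated correlation). Granule transcripts were high in db vehicle replicate 2, where S100a8 reached 199 TPM, Ngp 140 TPM and Elane 104 TPM, and Elane reached 69.2 TPM and Mpo 61.8 TPM in db BSO replicate 2. Without db vehicle replicate 2 the myeloid list reversed with an adjusted p of 0.683.

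The count of 53 fell to 16 without control vehicle replicate 2, 25 without db vehicle replicate 1 or replicate 2 and 31 without control vehicle replicate 1, and rose to 86 without control BSO replicate 2. Serpine2, Pf4, Il1b, Pls1, Rap1b, Myl10 and Vim passed without each library in turn, whereas Clu, F2rl2 and Cpne8 were lost without 8 of the 12, Hlf and Wbp1 without 9, Padi4 without 6, Rgs10, Alox5, Tspan17 and Tnfsf13os without 5, Rab27b without 4, Itga2b and Tmem98 without 3, Timp3 without 2, and Copz2, Sdf2l1 and Atp5f1 without control vehicle replicate 2. With no filter on low values, which tests more genes, the calls of Pf4, Rap1b, Itga2b, Rab27b, Timp3, Rgs10, Clu, Alox5, F2rl2, Padi4, Tspan17, Cpne8, Hlf, Wbp1 and Tnfsf13os were lost. Without a variance trend those of Rgs10, Clu, F2rl2, Cpne8 and Atp5f1 were lost, and median-ratio scaling ended those of Cpne8, Wbp1 and Tnfsf13os. The median of all genes was −0.13, and median-ratio scaling moved it by 0.14 and changed the split from 35 higher and 18 lower to 49 and 10.

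**Figure D1:**
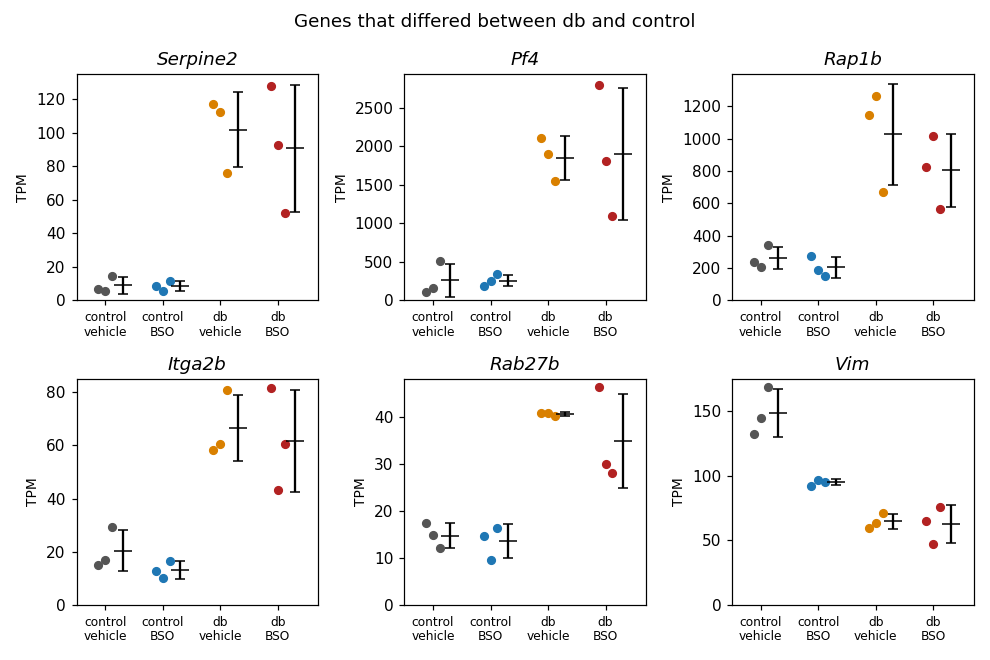
TPM of 6 genes that differed between db and control, with 1 point per library, 3 libraries per group, and the mean ± SD drawn beside the points. Each vertical axis is linear from 0; the db libraries lie above the control libraries of the same treatment for Serpine2, Pf4, Rap1b, Itga2b and Rab27b, and below them for Vim.

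The same genotype comparison in the presence of BSO gave 20 genes higher and 10 lower in db cells, 30 in all. At an unadjusted p under 0.05 there were 1127, with the opposite balance of 388 higher and 739 lower. Serpine2 was 8.51 ± 3.004 TPM in control BSO and 90.9 ± 37.9 TPM in db BSO (3.23 ± 0.37, adjusted p = 0.00305), and Pf4 was 257 ± 76.7 and 1899 ± 858 TPM (2.82 ± 0.45, adjusted p = 0.016). Il1b was listed at up to 0.0436 TPM in control BSO and at 8.76, 6.16 and 5.10 TPM in db BSO. Of the 15 megakaryocyte markers, 3 rose, again Pf4, Itga2b (2.13 ± 0.28, adjusted p = 0.00473) and Rab27b (1.29 ± 0.23, adjusted p = 0.0316), and 10 adjusted over the list alone. That list's median lay 1.54 above that of all genes (camera adjusted p = 1.08e-18, and adjusted p = 0.119 with an estimated correlation). Gata1, a transcription factor of erythroid and megakaryocytic cells, rose from 0.167 ± 0.196 to 4.69 ± 2.22 TPM (2.23 ± 0.37, adjusted p = 0.0211), the 1 of 6 erythroid markers to pass, with 0.00789 for the list (adjusted p = 0.203 with an estimated correlation). Cpa3, a mast cell protease gene, rose from 0.222 ± 0.194 to 5.26 ± 3.36 TPM, the 1 of 3 mast cell and basophil markers to pass, with 0.0245 for the list (adjusted p = 0.203 with an estimated correlation). Pls1, Alox5, Cavin2, Rap1b and Cst7 rose by 1.66 to 2.47. Myl10, Tinagl1, Pcp4l1, Tnfsf13os, Ypel3, Copz2, Dkkl1 and the lactate dehydrogenase subunit gene Ldhb fell, by between 0.61 and 1.96 on the log2 scale.

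In the lists with no single gene past the threshold, the 5 macrophage markers lay below 0 (camera adjusted p = 0.0020, and adjusted p = 0.203 with an estimated correlation). Of 79 cytosolic ribosomal protein genes 71 lay above 0 (3.68e-11, and adjusted p = 0.807 with an estimated correlation). Of 78 oxidative phosphorylation genes 55 lay above 0 (2.32e-04, and adjusted p = 0.807), and of 17 unfolded protein response genes 11 did (7.77e-04, and adjusted p = 0.807). None of the 7 lists past the camera threshold held with an estimated correlation. The count of 30 fell to 7 without db BSO replicate 1, 9 without db BSO replicate 2 and 16 without control BSO replicate 1. Serpine2, Il1b, Pls1, Itga2b and Cavin2 passed without each library in turn, whereas Ypel3 was lost without 11 of the 12, Copz2 without 10, Cpa3 and Pcp4l1 without 9, Rab27b and Tnfsf13os without 8, Dkkl1 without 7, Gata1 without 5, Pf4 without 4, Tinagl1 and Ldhb without 3, Rap1b and Myl10 without db BSO replicate 1 or replicate 2, and Alox5 and Cst7 without db BSO replicate 1. With no filter on low values the calls of Il1b, Pls1, Itga2b, Alox5, Rap1b, Myl10 and Tinagl1 were lost, and with no filter and also without a variance trend those of Pf4, Rab27b, Gata1, Cpa3, Tnfsf13os, Ypel3, Copz2 and Dkkl1. Ldhb was lost without a variance trend, and Tnfsf13os, Copz2, Dkkl1 and Ldhb under median-ratio scaling. Median-ratio scaling gave 43 higher and 13 lower in place of 20 and 10.

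Across the 10333 genes, the genotype effects with and without BSO correlated at a Pearson r of 0.57 and a Spearman rho of 0.51; genes are not independent replicates, and the comparisons share no libraries. There were 22 genes past the threshold in both, 17 higher and 5 lower, where independent lists would share 0.0677 and 0.0174. The 22 genes included Serpine2, Pf4, Il1b, Itga2b, Rab27b, Rap1b and Myl10.

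The next comparison asked how control HSC responded to BSO. Genes that rose included targets of NRF2, a transcription factor that responds to oxidants. Ftl1, the ferritin light chain (chromosome 7, 45457944 to 45459884, minus strand), rose from 9507 ± 196 to 23744 ± 654 TPM (1.32 ± 0.06, adjusted p = 1.32e-07), from 0.981% to 2.45% of the listed total. Nqo1, a quinone reductase (chromosome 8, 107388225 to 107403206, minus strand), rose from 42.9 ± 3.73 to 205 ± 92.9 TPM (2.14 ± 0.25, adjusted p = 8.32e-04), and Pir (chromosome X, 164269371 to 164373011, plus strand) from 2.43 ± 1.44 to 24.4 ± 5.20 TPM (2.95 ± 0.31, adjusted p = 3.69e-04). Of 25 NRF2 targets, 7 rose, among them the ferritin heavy chain Fth1 (0.96 ± 0.10), the biliverdin reductase Blvrb (1.65 ± 0.19) and the glutathione transferase Gstm1 (1.42 ± 0.15), and 10 adjusted over the list alone. The list's median lay 0.55 above that of all genes (camera adjusted p = 2.57e-26, and adjusted p = 0.00148 with an estimated correlation). Of 22 genes of glutathione synthesis and use, a list that shares members such as Gstm1 with the NRF2 targets, 2 rose (2.80e-08, and adjusted p = 0.0520 with an estimated correlation). Mgst2 (1.61 ± 0.31, adjusted p = 0.0465) and Gstm1 are glutathione transferases, whereas Gclc and Gclm, the subunits of the enzyme that BSO inhibits, had fold changes of 0.16 ± 0.28 (adjusted p = 0.836) and 1.16 ± 0.41 (adjusted p = 0.256). Of 19 antioxidant enzymes, the peroxiredoxins Prdx6 (0.90 ± 0.12) and Prdx1 (0.39 ± 0.05) rose (0.00931, and adjusted p = 0.299 with an estimated correlation). Hmox1 and Slc7a11 were 0.55 ± 0.35 and 0.20 ± 0.23, not past the threshold.

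Tnfsf4, Hpgds, Gdf15 and Ephx1 also rose, by 1.44 to 1.88. Genes that fell were Txnip, an inhibitor of thioredoxin and a FOXO target, from 245 ± 39.1 to 111 ± 6.06 TPM (−1.13 ± 0.19, adjusted p = 0.0219), the surface receptor Cd48 (−1.44 ± 0.25, adjusted p = 0.0247), the desaturase Scd1 (−1.26 ± 0.23, adjusted p = 0.0295) and the class I gene H2-Q6 (−0.71 ± 0.11, adjusted p = 0.0101). The class I gene H2-Q7 (−0.94 ± 0.18, adjusted p = 0.0532) and the asparagine synthetase gene Asns (−0.70 ± 0.14, adjusted p = 0.0610) did not pass. In all 27 genes rose and 4 fell, 31 of 10333, against 31 and 1 under median-ratio scaling and 39 and 11 under quantile normalization. At an unadjusted p under 0.05 there were 1457, with the opposite balance of 245 higher and 1212 lower.

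Several other lists passed the camera threshold in control cells without holding with an estimated correlation. The median of all genes was −0.15 there, so most genes of any kind lay below 0. ATF4 targets, which serve amino acid synthesis and stress, lay below 0 in 25 of 26 (camera adjusted p = 2.42e-07, and adjusted p = 0.299 with an estimated correlation), with 10 lower adjusted over the list alone and none over all genes. Mitochondrially encoded mRNAs lay below 0 in 13 of 13 (7.74e-07, and adjusted p = 0.299), with 9 lower adjusted over the list alone. Cholesterol synthesis genes lay below 0 in 19 of 19 (7.40e-04, and adjusted p = 0.538), interferon response genes in 19 of 19 (0.00399, and adjusted p = 0.299) and fatty acid synthesis genes in 11 of 13, of which Scd1 fell (0.00119, and adjusted p = 0.358). Ribosomal protein genes lay below 0 in 66 of 79 (7.42e-04, and adjusted p = 0.893), but their median of −0.14 lay only 0.00599 from that of all genes, and median-ratio scaling, which moved the median of all genes by 0.16, made it 0.03. Macrophage markers lay above 0 in 3 of 5 (0.0161, and adjusted p = 0.299). Oxidative phosphorylation genes tested upward (0.0109, and adjusted p = 0.893) with a median of 0.01 and a mean of −0.03, which differ in sign. The count of 31 rose to 54 without control vehicle replicate 1, fell to 20 without control vehicle replicate 3, and was 14 with only the 2 groups compared. Pir, Nqo1, Tnfsf4, Blvrb, Gdf15, Gstm1, Ftl1, Fth1, Prdx6 and Prdx1 passed without each library in turn, whereas H2-Q6 was lost without control vehicle replicate 3, Hpgds and Ephx1 without 3 of the 12, Txnip and Cd48 without 5, Scd1 without 7 and Mgst2 without 9. Median-ratio scaling ended the calls of Cd48, Scd1, H2-Q6 and Prdx1. Prdx1, Prdx6, Txnip and Mgst2 were lost without a variance trend, and Prdx6, Txnip, Cd48, Scd1, Hpgds, Ephx1 and Mgst2 with no filter on low values.

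**Figure D2:**
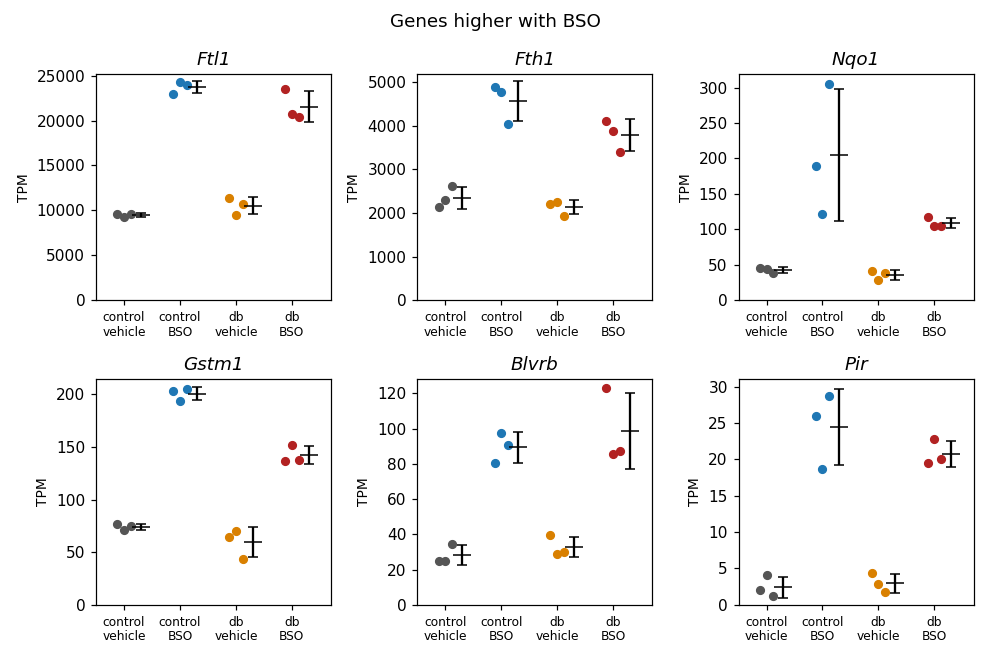
TPM of 6 genes higher with BSO, with 1 point per library, 3 libraries per group, and the mean ± SD drawn beside the points. Each vertical axis is linear from 0; in both genotypes the BSO libraries lie above the vehicle libraries for each of the 6 genes.

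BSO in db HSC gave 24 genes higher and 0 lower, with 504 at an unadjusted p under 0.05, of which 336 were lower. Ftl1 rose from 10541 ± 919 to 21541 ± 1734 TPM (1.03 ± 0.06, adjusted p = 3.35e-06), Pir from 2.96 ± 1.34 to 20.7 ± 1.75 TPM (2.51 ± 0.31, adjusted p = 0.00248) and Nqo1 from 36.2 ± 6.91 to 109 ± 7.45 TPM (1.58 ± 0.25, adjusted p = 0.0158). Cyb5a, cytochrome b5, rose from 574 ± 18.4 to 1019.5 ± 8.94 TPM (0.83 ± 0.07, adjusted p = 1.32e-04). Of 25 NRF2 targets, 7 rose, among them Blvrb, Gstm1, Fth1 and Gsta4, and 11 adjusted over the list alone (camera adjusted p = 4.72e-36, and adjusted p = 4.64e-04 with an estimated correlation). Of 22 genes of glutathione synthesis and use, 2 rose (7.23e-11, and adjusted p = 0.0227 with an estimated correlation). Those 2, Gstm1 and Gsta4, are also NRF2 targets. Gclc, Gclm, Gsr, Gstp1 and Mgst1 are on both lists as well, so this result partly repeats that of the NRF2 list. Gclc was −0.19 ± 0.28 and Gclm 0.97 ± 0.41, neither past the threshold. Of 19 antioxidant enzymes, Prdx6 rose (0.00158, and adjusted p = 0.259 with an estimated correlation). Of 22 p53 targets, 1 rose, the apoptosis gene Bax (0.45 ± 0.08, adjusted p = 0.037), with 6.16e-05 for the list (adjusted p = 0.271 with an estimated correlation). The 3 mast cell and basophil markers lay above 0, none past the threshold (1.78e-04, and adjusted p = 0.0330 with an estimated correlation). With no filter on low values, which tests more of the list's 11 members, this call was lost (adjusted p = 0.0704, the highest over its alternatives, against a lowest of 1.87e-06).

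The median of all genes was −0.11 with BSO in db cells, so most genes of any kind lay below 0. Lists shifted downward by camera in db cells had no member that fell singly and did not hold with an estimated correlation. They were ATF4 targets, 24 of 26 below 0 (8.59e-09, and adjusted p = 0.259 with an estimated correlation), cholesterol synthesis, 19 of 19 (2.34e-06, and adjusted p = 0.410), fatty acid synthesis, 11 of 13 (0.00158, and adjusted p = 0.418), mitochondrially encoded mRNAs, 12 of 13 (0.00270, and adjusted p = 0.639), and interferon response, 17 of 19 (0.00665, and adjusted p = 0.410). No single gene passed downward, and those with the smallest p were the sterol synthesis gene Fdps (−0.37 ± 0.08, adjusted p = 0.116), Siah2 (−1.16 ± 0.25, adjusted p = 0.144), the desaturase Scd2 (−1.01 ± 0.23, adjusted p = 0.197), Rabep2 (−1.15 ± 0.27, adjusted p = 0.204) and Txnip (−0.81 ± 0.19, adjusted p = 0.232). Hmox1 and Slc7a11 were 1.11 ± 0.35 and 0.31 ± 0.23, not past the threshold. The count of 24 fell to 7, 9 and 10 without db BSO replicates 1, 2 and 3, to 15, 8 and 10 without db vehicle replicates 1, 2 and 3, and to 10 without a variance trend. Pir, Blvrb, Gstm1, Ftl1, Fth1 and Cyb5a passed without each library in turn, whereas Tnfsf4 was lost without 4 of the 12, Nqo1, Ephx1 and Prdx6 without 5, Gsta4 without 7 and Bax without 10. Nqo1, Gsta4, Fth1, Prdx6 and Bax were lost without a variance trend, Nqo1, Tnfsf4, Ephx1, Gsta4, Prdx6 and Bax with no filter on low values, Bax under median-ratio scaling and Prdx6 under quantile normalization.

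The BSO effects in the 2 genotypes correlated across genes at a Pearson r of 0.39 and a Spearman rho of 0.40, with no libraries shared. There were 19 genes past the threshold in both, all higher, where independent lists would share 0.0627. Among them were Ftl1, Fth1, Nqo1, Pir, Blvrb, Gstm1, Prdx6, Cyb5a, Ephx1 and Tnfsf4. The 19 also held the pseudogene Ftl1-ps1 and the predicted gene Gm5526. Reads may be split between Ftl1 and its copies, so its signal may be counted more than 1 time. Here too the variance of each gene came from all 12 libraries, so the 2 sets of calls are not independent and 0.0627 is only a rough reference. Of the 31 genes called in control cells 30 had the same sign in db cells, and of the 24 called in db cells 24 had the same sign in control cells.

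**Figure D3:**
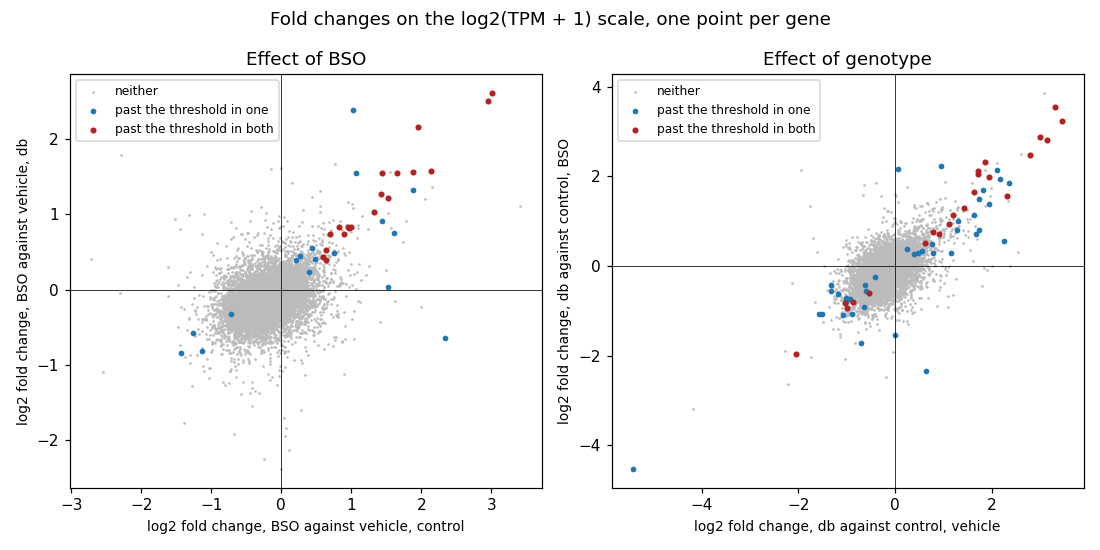
Log2 fold changes on the log2(TPM + 1) scale for 10333 genes, with BSO against vehicle in control cells on the horizontal axis and in db cells on the vertical axis (left), and db against control with vehicle and with BSO (right). Points mark genes past the threshold in both comparisons, 19 on the left and 22 on the right, in one, or in neither.

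Whether BSO acted differently in the 2 genotypes was tested directly. By limma no gene passed (0 of 10333, smallest adjusted p = 0.851), with 249 at an unadjusted p under 0.05. Among genes with the smallest p under the level filter, the prostaglandin synthase Hpgds had a difference of −1.49 ± 0.36, Gbp3 1.43 ± 0.36, Cpa3 2.10 ± 0.55 and Ftl1 −0.29 ± 0.09, none past the threshold. The others were Prr3 (0.93 ± 0.28), Spin2c (1.24 ± 0.39), Cbx6 (1.10 ± 0.35), Ctsh (−1.28 ± 0.37), Pdcd4 (−0.87 ± 0.27) and Fam210a (−0.87 ± 0.28), also not past it. By camera, ribosomal protein genes (65 of 79 above 0, adjusted p = 3.32e-04) and mitochondrially encoded mRNAs (11 of 13 above 0, adjusted p = 0.0106) differed upward in db cells, with no member past the threshold and an adjusted p of 0.989 for each with an estimated correlation. The ribosomal list had an adjusted p of 0.935 without control vehicle replicate 3 and 0.227 under median-ratio scaling.

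The series title concerns FOXO factors. Foxo3 (chromosome 10, 42181841 to 42276755, minus strand) was 7.31 ± 1.10 TPM in control vehicle, 6.53 ± 0.214 in control BSO, 4.40 ± 0.984 in db vehicle and 4.59 ± 1.21 in db BSO, and its genotype fold change of −0.63 ± 0.24 with vehicle had an adjusted p of 0.257. Its fold changes were −0.45 ± 0.24 for db against control with BSO, −0.13 ± 0.24 for BSO in control cells and 0.04 ± 0.24 in db cells, with a difference of 0.18 ± 0.33, none past the threshold. Foxo1 was near 1 TPM in each group and its fold changes lay between −0.23 and 0.15, none past the threshold. Foxo4 lay below the filter, at 0.0978 TPM over all libraries. Of 25 tested FOXO targets none passed except Txnip, which fell with BSO in control cells. For db against control, Txnip was 245 ± 39.1 TPM in control vehicle and 144 ± 22.5 TPM in db vehicle (−0.77 ± 0.19, adjusted p = 0.102), and −0.45 ± 0.19 with BSO (adjusted p = 0.420), with a difference of BSO effects of 0.32 ± 0.27. The list's adjusted p was 0.401 for db against control with vehicle, 0.342 with BSO, 0.954 for BSO in control cells, 0.825 in db cells and 0.915 for the difference. With BSO in control cells the list's median of −0.10 and the upward direction of the test differed in sign, and the median was 0.05 under median-ratio scaling and 0.11 under quantile normalization. The HSC list had adjusted p-values of 0.636, 0.446, 0.518, 0.239 and 0.867 in the same order. Its stem cell surface gene Procr and regulator Mecom had fold changes of −0.47 ± 0.29 and −0.47 ± 0.34 for db against control with vehicle, and −0.44 ± 0.29 and −1.18 ± 0.34 with BSO (adjusted p = 0.205 for Mecom). Procr was 0.07 ± 0.29 for BSO in control cells and 0.10 ± 0.29 in db cells, and Mecom 0.11 ± 0.34 and −0.60 ± 0.34. Cdkn1a, a cell cycle inhibitor, did not pass in any comparison, at 0.23 ± 0.22 for db against control with vehicle, 0.37 ± 0.22 with BSO, 0.38 ± 0.22 for BSO in control cells, 0.52 ± 0.22 in db cells and 0.14 ± 0.31 for the difference. For db against control, Gclc, Gclm, Nqo1, Hmox1 and Slc7a11 did not pass either. With vehicle Gclc was 0.73 ± 0.28, Gclm 1.0 ± 0.41, Nqo1 −0.25 ± 0.25, Hmox1 −0.93 ± 0.35 and Slc7a11 −0.10 ± 0.23, and with BSO they were 0.38 ± 0.28, 0.82 ± 0.41, −0.81 ± 0.25, −0.37 ± 0.35 and 0.01 ± 0.23. Their differences of BSO effects were −0.35 ± 0.39, −0.18 ± 0.59, −0.56 ± 0.35, 0.55 ± 0.49 and 0.11 ± 0.33, and those of Procr and Mecom 0.03 ± 0.41 and −0.71 ± 0.48.

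No other fixed list passed the threshold in any of the 5 comparisons. These were apoptosis regulators, autophagy, B and T cell markers, CDK inhibitors and quiescence, fatty acid oxidation, G1/S genes, G2/M genes, glycolysis, heat shock, HIF targets, histone genes, immediate early genes, multipotent and lymphoid progenitor genes, and the NF-kB response, with a lowest adjusted p of 0.0501.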

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

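The tests of possible explanations in this part were chosen after the results had been seen, except the counts over other splits of the libraries. The difference of BSO effects between genotypes singled out 2 lists by camera, ribosomal protein genes (adjusted p = 3.32e-04) and mitochondrially encoded mRNAs (adjusted p = 0.0106), as a difference between groups. Other explanations may account for the ribosomal list, the only one of the 2 for which they were tested in this part. They stay open for the mitochondrial list. With an estimated correlation, which allows for genes of a list varying together, the ribosomal list's adjusted p was 0.989. Leaving out control vehicle replicate 3 gave 0.935, and median-ratio scaling gave 0.227. Of 100 splits of the libraries, 91 gave at least the 2 lists of the real grouping and the highest gave 16. Treatment labels were shuffled within each genotype, so a split can carry the BSO effect common to both genotypes into the difference. These splits therefore cannot measure chance here, and chance is not excluded. A biological difference in the response to BSO stays open, untested beyond this.

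The megakaryocyte list passed by camera for db against control in both treatments, with 3 of 15 members past the threshold in each. The call was lost with an estimated correlation (adjusted p = 0.212 with vehicle and 0.119 with BSO). Scaling between libraries is argued against, since the list's median stayed at 1.35 or more under both scalings in both treatments. Fewer detected genes are argued against as the whole cause, since control BSO libraries also list fewer genes than control vehicle and their list median was −0.17. A candidate explanation is cells of the megakaryocyte lineage among the cultured cells, since 14 of 15 markers lay above 0 in each treatment, which largely restates the pattern, and a change of expression within HSC would give the same. The library index cannot be told apart from genotype, because 0 i5 indexes were used in both.

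Granule transcripts were high in db vehicle replicate 2 (S100a8 199, S100a9 94.9, Ngp 140, Camp 56.5 and Elane 104 TPM). Part of this was shared with db BSO replicate 2, where Mpo was highest of all libraries at 61.8 TPM, Elane was 69.2, Ctsg 25.3, Ms4a3 10.8 and Ly6c2 10.1 TPM, and Mpo was 47.9 TPM in control BSO replicate 3. RNA of granulocyte precursors or neutrophils may be its source. Of 11 other neutrophil markers, chosen after the values were seen, the 4 that reached 1 TPM (Ltf, Lcn2, Chil3 and Wfdc21) were highest in db vehicle replicate 2. The other 7 stayed under 1 TPM everywhere. Of these, Retnlg, Mmp8, Mmp9 and Ly6g were listed at 0 in db vehicle replicate 2. Cd177 and Ifitm6 were highest there, at 0.290 and 0.725 TPM, and Mcemp1 was 0.651 TPM there. Csf3r, on the fixed myeloid list, went the other way. It was lowest of all libraries in db vehicle replicate 2, at 0.253 TPM, and at most 0.380 TPM in db vehicle. The SLAM sort would remove mature neutrophils, and cells made in culture stay open. The myeloid list call rested on db vehicle replicate 2, with an adjusted p of 0.683 without it.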

How the results depend on the processing

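The alternatives were planned except the gene-by-gene sample weights, which were chosen after seeing the data. Causes were not tested unless given. Depth is unknown, so its limit cannot be set. Of the 73 calls of named genes, 28 were kept without each library in turn, and 20 also under each other alternative run for them. For the 35 list calls the numbers were 19 and 3. The fit of only the 2 groups compared and the gene-by-gene weights were run for gene counts alone, so these figures leave them out. Of the 73, 43 were lost with no filter, 23 without a variance trend, 12 under median-ratio scaling, 9 under quantile normalization, and 8 and 6 with pseudocounts of 0.1 and 5. Quantile normalization ended, among others, Cpne8 and Wbp1 for db against control with vehicle and Cd48 with BSO in control cells. It also ended Pcp4l1, Tnfsf13os, Copz2 and Dkkl1 for db against control with BSO. A pseudocount of 5 ended, among others, Clu and F2rl2 in the first comparison, Cd48 and Mgst2 in the second and Cpa3 in the last. A left-out library leaves 2 in its group.

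Genes past the threshold for db against control with vehicle (53) numbered 25 with no filter on low values, 103 under quantile normalization, 570 with sample weights and 380 with gene-by-gene weights (136 higher, 244 lower). BSO in control cells (31) gave 50 under quantile normalization, 1717 with sample weights, 213 with gene-by-gene weights (61 higher, 152 lower) and 14 with only the 2 groups compared. BSO in db cells (24) gave 10 without a variance trend, 43 with sample weights and 41 with gene-by-gene weights. Db against control with BSO (30) gave 9 with no filter, 16 without a trend, 56 under median-ratio scaling, 58 under quantile normalization, 664 with sample weights, 71 with gene-by-gene weights and 13 with only the 2 groups. The difference of BSO effects (0) gave 1 with no filter. Lists (35) fell to 4 with an estimated correlation, which widens the test where the estimate exceeds the preset of 0.01, and 12 with fry, which does not compare a list with other genes. The default sample weights stopped before converging and ran from 0.281 (control BSO replicate 2) to 4.93 (control BSO replicate 1), so those counts are not to be relied on; gene-by-gene weights ran from 0.321 to 2.21. Median-ratio scaling moved the median of all genes by 0.14, 0.16 and 0.11 in the first 3 of these comparisons, and quantile normalization by 0.17, 0.20, 0.13 and 0.11 in the first 4.

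Without 1 library at a time, the counts ranged from 16 (without control vehicle replicate 2) to 86 (control BSO replicate 2) for db against control with vehicle, 20 (control vehicle replicate 3) to 54 (control vehicle replicate 1) for BSO in control cells, 7 (db BSO replicate 1) to 29 (control BSO replicate 2) for BSO in db cells, 7 (db BSO replicate 1) to 39 (db BSO replicate 3) for db against control with BSO, and 0 to 1 (db BSO replicate 3) for the difference. Lists ranged from 35 to 43. The correlation of BSO effects ranged from 0.23 to 0.41 and that of genotype effects from 0.45 to 0.60.

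The replicate block gave 50, 31, 19, 29 and 0 genes in the same order and 39 lists; it ended 8 of the 73 calls of named genes and none of the 35 of lists. Those 8 were Cpne8, Hlf and Wbp1 for db against control with vehicle, Mgst2 with BSO in control cells, Bax with BSO in db cells, and Pcp4l1, Ypel3 and Copz2 for db against control with BSO. Replicate numbers were not taken to pair the libraries, a choice fixed beforehand because the labels state no pairing. The correlations of deviations did not settle it. Of 18 same-number pairs, 7 had a correlation over 0.1, and all ranged from −0.28 to 0.28. The best match had its own number in 15 of 36, and with 3 libraries per group many such matches arise by chance. Between db vehicle and db BSO the correlations were 0.0266, 0.281 and 0.182 for numbers 1, 2 and 3, and both libraries numbered 2 held Elane and Ctsg, so a shared origin of some same-numbered db libraries stays open.

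No named gene past the threshold reversed. With BSO in control cells, the FOXO targets list reversed with no filter (adjusted p = 0.892), median-ratio scaling (0.986), sample weights (0.879) and fry (0.420), and the oxidative phosphorylation list, a call, with fry (0.872). For the difference, FOXO targets reversed with sample weights (0.911) and fry (0.978), and HSC genes with fry (0.978). Log2 fold changes that reversed under median-ratio scaling were Lyz2 (0.083) and Foxo3 (0.017) with BSO in control cells and Procr (−0.018) for the difference. Under quantile normalization they were Foxo3 (0.13) with BSO in control cells, Foxo1 (0.043) with BSO in db cells, Slc7a11 (0.063) for db against control with vehicle, and Ftl1 (0.059) and Procr (−0.11) for the difference. With sample weights they were Lyz2 (0.059) and Foxo1 (0.11) with BSO in control cells, Car2 (−0.18) and Foxo1 (−0.10) for db against control with BSO, and Foxo1 (−0.17) for the difference. With a pseudocount of 5, Procr (−0.011) reversed for the difference.

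Leaving out single libraries reversed further results, given as ranges. For db against control with vehicle, Foxo1 ranged from −0.088 to 0.094, Slc7a11 from −0.24 to 0.088 and the myeloid list's adjusted p from 1.01e-05 to 0.683 (db vehicle replicate 2). With BSO in control cells, Procr ranged from −0.054 to 0.15, Mecom from −0.046 to 0.33, and adjusted p from 0.685 to 0.998 for FOXO targets, 4.90e-15 to 0.814 for ribosomal proteins (reversed without control BSO replicate 3, lost without control vehicle replicate 3) and 9.74e-10 to 0.642 for oxidative phosphorylation (reversed without control BSO replicate 2, lost without control vehicle replicate 1). With BSO in db cells, Foxo1 ranged from −0.24 to 0.059, Foxo3 from −0.11 to 0.23, Gclc from −0.54 to 0.028, Procr from −0.15 to 0.46 and FOXO targets from 0.576 to 0.9998. For db against control with BSO, Mcpt8 ranged from −0.75 to 0.14, Car2 from −0.018 to 0.21, Hbb-bs from −0.60 to 0.91 and Slc7a11 from −0.082 to 0.097. For the difference, Foxo1 ranged from −0.0050 to 0.32, Gclm from −0.65 to 0.20, Slc7a11 from −0.073 to 0.25, Cdkn1a from −0.078 to 0.34, Procr from −0.23 to 0.39, and adjusted p from 0.741 to 0.974 for FOXO targets, 0.635 to 0.974 for HSC genes and 1.94e-17 to 0.935 for ribosomal proteins (reversed without control BSO replicate 3, lost without control vehicle replicate 3 and db vehicle replicate 1).

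Of the remaining calls, lists lost without a single library were erythroid markers for db against control with vehicle (control vehicle replicate 1, db vehicle replicate 1) and with BSO (control BSO replicate 3, db BSO replicate 1); antioxidant enzymes (control BSO replicate 1), macrophage markers (control vehicle replicate 1, control BSO replicates 1 and 2) and interferon response (control vehicle replicate 3) with BSO in control cells; mitochondrially encoded mRNAs and interferon response (db vehicle replicate 2) with BSO in db cells; and the unfolded protein response (control BSO replicate 2), mast cell markers (control BSO replicate 3, db BSO replicate 2), ribosomal proteins and oxidative phosphorylation (control BSO replicate 3) for db against control with BSO. Mitochondrially encoded mRNAs for the difference of BSO effects were lost without control vehicle replicate 3, control BSO replicate 3, db vehicle replicates 1 and 3 and db BSO replicate 3, with a highest adjusted p of 0.691.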

Other observations

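The tests of class I genes and of the region around Lepr were chosen after the results had been seen; the splits of libraries were planned. Class I major histocompatibility genes were not among the fixed lists. Of 12 tested, 12 lay below 0 with BSO in control cells, with a median of −0.35 and H2-Q6 the 1 that fell, a call lost under median-ratio scaling and without control vehicle replicate 3 (unadjusted camera p = 6.92e-04, and p = 0.0319 with an estimated correlation). For db against control with vehicle 11 of 12 lay below 0, with a median of −0.37 and none past the threshold (unadjusted camera p = 5.81e-04, and p = 0.0302 with an estimated correlation). With BSO in db cells 8 of 12 lay below 0 (p = 0.00764, and p = 0.0757 with an estimated correlation), and for db against control with BSO 9 of 12 did (p = 0.0222, and p = 0.119). For the difference of BSO effects 3 of 12 lay below 0. Camera gave an upward direction there (unadjusted p = 0.0888, and p = 0.230 with an estimated correlation). These H2 genes share sequence, so how reads were divided among them is uncertain. The median of all genes also lay below 0, at −0.15 with BSO in control cells and −0.13 for db against control with vehicle. Counts of class I genes below 0 may partly follow it.

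A db mutation kept by crossing could bring along neighbouring DNA. Within 20 Mb of Lepr, 12.1% of 165 genes had an unadjusted p under 0.05 for db against control with vehicle, against 14.7% elsewhere, a ratio of 0.823 (Fisher's exact test, two-sided, p = 0.437), and with BSO the ratio was 0.716 (p = 0.257). Of the 53 genes called, 1 lay there, Efcab7, named after its values were seen. No excess of changed genes was thus seen near Lepr. A linked variant could also change genes elsewhere, so this test cannot decide whether linked DNA is a cause of the genotype differences.

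Splitting the 6 libraries of a comparison into 3 and 3 gives 10 splits, too few for a share under 0.05. The real grouping gave 53 genes for db against control with vehicle and the highest other split 1, with 1 of 10 splits as large. The figures were 24 and 0 for BSO in db cells (1 of 10) and 30 and 1 for db against control with BSO (1 of 10). For BSO in control cells the real grouping gave 31 and another split 61, so 2 of 10 were as large. That split set control vehicle replicates 2 and 3 with control BSO replicate 2 against the remaining 3, which points to a structure among these libraries other than treatment. For the difference of BSO effects the real grouping gave 0 genes, a number that all 100 of 100 splits reach by definition, so the count of splits says nothing there. The highest other split gave 510. Treatment labels were shuffled within each genotype there, so the BSO effect common to both genotypes can enter the difference. The 510 therefore cannot be told apart from that effect or from a structure among the libraries.

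Lists gave less contrast between real and other splits. The real grouping gave 5 lists for db against control with vehicle and another split up to 11 (5 of 10 as large), 11 and 13 for BSO in control cells (3 of 10), 10 and 11 for BSO in db cells (4 of 10), and 7 and 10 for db against control with BSO (4 of 10). The medians of the other splits were lower than the real values, at 4, 6, 7 and 5 lists, but some groupings that cut across the labels gave at least as many.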
